A study of Arabidopsis thaliana with 24 samples.

How the data were processed

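Messenger RNA was measured by sequencing in 24 libraries from whole Arabidopsis thaliana seedlings of 4 genotypes, each grown with or without abscisic acid (ABA, a stress hormone) at 5 µM for 24 h. Each of the 8 combinations had 3 replicates. The sample labels give an age of 5 days before the treatment, whereas the design text of the series gives 6 days of growth and 1 day of treatment, hence 7 days at harvest; which is right is not given in the sources used here. The labels do not say whether the replicates came from separate cultures, so the p-values measure the spread between these samples.

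The deposited values are FPKM (fragments per kilobase of exon, scaled to the mapped fragments of the library), rounded by the authors to 2 decimals, in 1 file per library with 32833 genes each. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.30 and aligned with HISAT2 2.0.1 to the TAIR10 build. The extract protocol names poly(A) selection or rRNA removal without saying which library had which. The read counter, the annotation and the strand setting are not given in the sources used here. Of the gene identifiers, 32548 matched the TAIR10.1 table that gave symbols and coordinates; organelle identifiers did not match it. Symbols are those of that table or of the gene lists fixed beforehand.

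Depth was read from the values themselves. In genes with a single transcript shorter than 400 bases, FPKM times exon length moves in steps of 1 fragment, and the step gave 16.6 to 29.1 M fragments per library (median 19.3 M). With that step, 99.8% to 100% of the values tested in each library lay within 0.1 of a whole fragment. FPKM was used as deposited, with no further scaling, as log2(FPKM + 1). Genes with FPKM of at least 1 in at least 3 libraries were tested, which left 19500.

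Differences were tested with limma 3.58.1 in R 4.3.3. A single model with a mean for each of the 8 groups was fitted over all 24 libraries, with empirical Bayes moderation and an intensity trend. The tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the genes tested within each of 15 comparisons. Genes with an adjusted p under 0.05 are called higher or lower. The 15 comparisons, their tests, the gene lists, the rule for named genes and the other settings to be tried were fixed before the data were examined. The comparisons are the ABA response within each genotype, 4 comparisons between genotypes without ABA, the same 4 with ABA, and 3 differences between ABA responses.

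For 6 main comparisons, the named genes are the 5 with the largest rise and the 5 with the largest fall among genes called, with a mean FPKM of at least 5 in the higher group, no overlap between the groups and a symbol, and up to 3 called members of each list with the smallest adjusted p. The main comparisons are the ABA response in WT, nrp1 nrp2 against WT without and with ABA, FyPP3DN against WT without ABA, nrp1 nrp2 FyPP3DN against nrp1 nrp2 with ABA, and the difference of the ABA response between nrp1 nrp2 and WT. The other comparisons name genes already named and up to 3 per direction by the same criteria. The genes targeted by the lines were followed in every comparison. Some genes of the rule were left out for length. Genes outside the rule are said to be chosen after their values were seen.

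24 lists with 358 genes were fixed. They covered ABA-responsive genes, clade A PP2C phosphatases, ABA receptors, ABA metabolism, seed maturation, Aux/IAA, GH3 and SAUR genes, auxin transport, auxin synthesis, auxin receptors and ARFs, cell wall expansion, PP6 and PP2A subunits, the cell cycle, photosynthesis, root hairs, root tissue, the stomatal lineage, salicylic acid and immunity, jasmonate, type-A ARR genes, heat shock, flavonoids and the circadian clock. Each was tested against all other genes with camera, with the correlation between its genes estimated from the residuals, and adjusted over the 24 lists within a comparison. A list is called when that adjusted p is under 0.05. The number of called members is given over all genes tested and adjusted over the list alone. Alternatives were camera with a preset correlation of 0.01, and fry, which asks whether a list's own genes move and does not compare them with other genes.

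The share of FPKM from plastid-encoded genes divided the libraries into 8 plastid-rich and 16 plastid-poor ones, with 1 plastid-rich and 2 plastid-poor libraries in each group. A repeat with this library type as a block and a repeat on the plastid-poor libraries alone were added after seeing the data, and their counts stand beside the pooled ones. Because the types are balanced over the groups, the block leaves every log2 difference as it is and changes only its spread. Replicate numbers were checked for pairing. In the 12 comparisons without the FyPP3DN control group, residuals of libraries with the same number correlated at 0.153 to 0.858 across genes, whereas in the 3 comparisons with that group the lowest value was -0.677. The plastid-rich library is replicate 1 in 7 groups and replicate 2 in the FyPP3DN control group. After removal of the library type, the median same-number correlation of a comparison lay between -0.350 and 0.339. Genes are not independent replicates in these correlations.

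The settings chosen beforehand were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, a fold of at least 2, median-of-ratios scaling, quantile normalization, removal of organelle genes with rescaling, moderation without a trend, a replicate block, a fit of only the groups compared, and leaving out each library in turn. Where comparisons share libraries, correlations, covariances and signs were set beside 20 simulations of unchanged groups that share libraries in the same way. The model was tested on simulated data with 100 genes changed by each of 2 sizes. For nrp1 nrp2 against WT, 84% of changes of 1 on the log2 scale and 99% of changes of 2 were recovered. For the difference of the ABA response between FyPP3DN and WT, these were 58% and 98%. With the library type block the 4 values were 90%, 100%, 72% and 100%, and false calls were at most 3.55% of all calls. All these simulations gave a gene the same spread and library type shift in every group, with genes independent. The rates may therefore not hold for FyPP3DN. There, a fit of only the groups compared lowered the ABA response from 1161 to 236 genes. A score of the ABA response, the contrast between the effects labelled FyPP3DN in both backgrounds, and the genes of the closing section that mark lines were also added after seeing the data.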

Results

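Transcript levels were measured in whole seedlings of wild type (WT, Columbia 0), the double mutant nrp1 nrp2, the line FyPP3DN, which carries a dominant-negative form of FYPP3 (a catalytic subunit of the phosphatase PP6), and their combination nrp1 nrp2 FyPP3DN. Each genotype was grown with and without ABA, with 3 libraries in each of 8 groups. The series title places NRP upstream of FyPP3 in the repression of growth by ABA, so the comparisons ask which genes responded to ABA, which differed between genotypes, and whether the combination shifted what nrp1 nrp2 changed. Depth was 16.6 to 29.1 M fragments per library, and 17893 to 18470 genes had FPKM of at least 1.

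In every group, 1 library was rich in plastid-encoded transcripts and 2 were poor. Plastid-encoded genes held 9.61% to 18.8% of the summed FPKM in the 8 plastid-rich libraries and 0.0252% to 0.0877% in the 16 plastid-poor ones. The 10 most abundant genes held 13.4% to 19.3% and 7.99% to 11.3% of the sum, respectively. Library type accounted for 95.3% of the first principal component, which held 37.4% of the variance, and ABA accounted for 96.6% of PC2, which held 25.3%. Within a group, libraries of the same type correlated across genes with a median r of 0.989, and libraries of different types with a median r of 0.960. Among nuclear genes, the plastid-rich libraries had median log2 differences of -0.52 for root hair genes (-1.25 to 0.117 over the groups), -0.48 for root tissue markers (-0.724 to 0.171), -0.19 for photosynthesis genes (-0.283 to 0.013) and 0.38 for SAUR genes (0.0883 to 0.681). Auxin receptors and ARFs (-0.261, -0.448 to -0.134) and auxin transport genes (-0.207, -0.305 to -0.0862) were lower in every group. Because the types were balanced over the groups, counts with the library type as a block and counts from the plastid-poor libraries alone stand beside each pooled count.

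**Figure D1:**
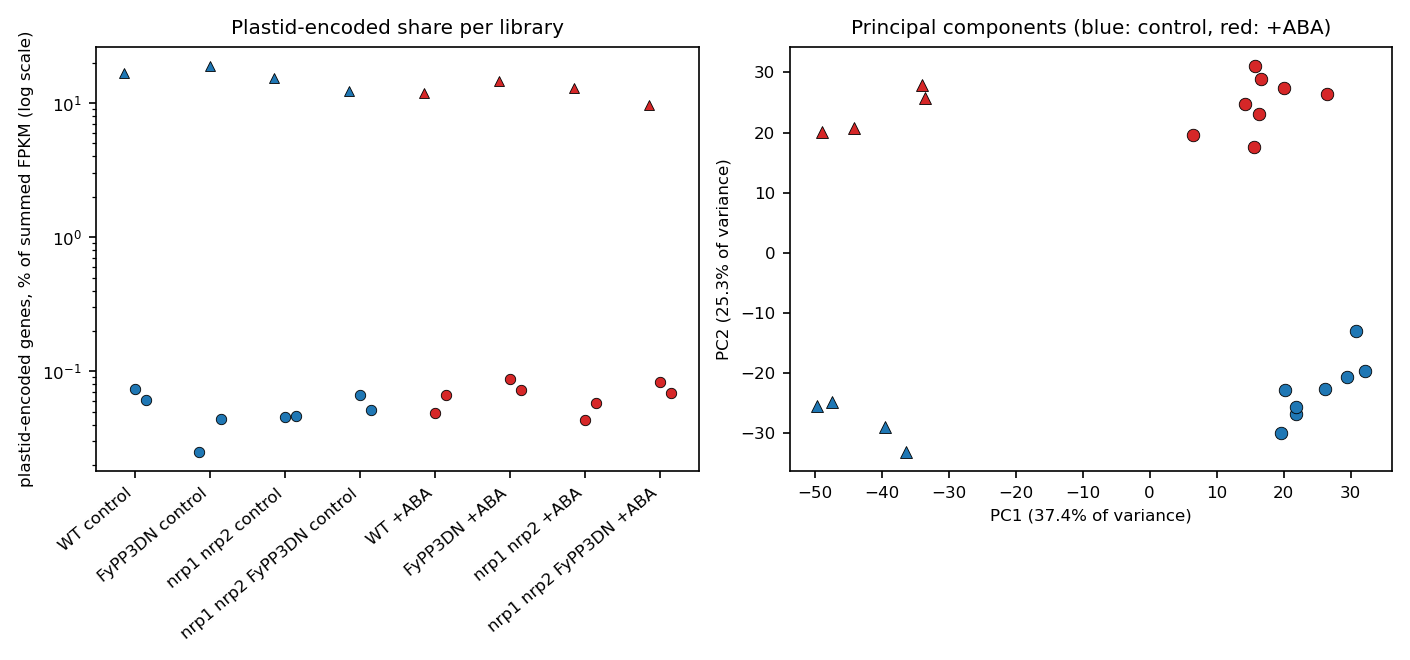
Left, the share of summed FPKM from plastid-encoded genes (%, log scale) in each library by group; right, the libraries on principal components 1 and 2, with control libraries in blue and libraries with ABA in red. The 8 plastid-rich libraries, 1 in each group, lie apart from the other 16 in both panels.

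FYPP3 was raised in the libraries labelled FyPP3DN without ABA and not in those of the combination. FYPP3 (AT3G19980, chromosome 3, 6961736 to 6965206) had an FPKM of 15.6 ± 2.82 (SD, n = 3) in WT and 55.5 ± 26.4 in FyPP3DN without ABA, with a lowest value of 34.5 in FyPP3DN. In the libraries labelled nrp1 nrp2 FyPP3DN it was 13.1 ± 0.38 without ABA and 16.9 ± 1.89 with ABA, beside 15.3 ± 0.22 and 16.9 ± 0.98 in nrp1 nrp2. The FyPP3DN effect on FYPP3 differed between the nrp1 nrp2 and the WT background without ABA (log2 -1.90 ± 0.28 SE, adjusted p = 0.00194, a contrast added after the values were seen). With ABA, FYPP3 was at 25.6 ± 3.42 in FyPP3DN and 16.3 ± 0.36 in WT, and neither the difference between these groups (log2 0.61 ± 0.20, adjusted p = 0.214) nor the difference between backgrounds (-0.61 ± 0.28, adjusted p = 0.478) passed the test. The combination is therefore called by its label below, and no direction drawn from it is a measured effect of FyPP3DN.

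The labels give no locus for nrp1 and nrp2, and 2 gene pairs carry such names. Of these 4 genes, 1 was lower in the libraries labelled nrp1 nrp2, so the transcripts do not show the loss of a second gene. AT3G27090 (chromosome 3, 9989511 to 9991903), of the DCD-domain pair, fell from 67.4 ± 1.73 in WT to 20.03 ± 1.23 in nrp1 nrp2 and 17.77 ± 1.71 in the libraries labelled nrp1 nrp2 FyPP3DN, and stood at 68.1 ± 3.25 in FyPP3DN (without ABA, n = 3 each). The log2 difference from WT was -1.70 in nrp1 nrp2 (adjusted p = 3.4e-10) and -1.87 in the labelled combination, and with ABA it was -2.37 and -2.38. Its pair AT5G42050 was at 30.9 ± 1.15 in WT, 57.3 ± 12.9 in nrp1 nrp2 and 67.9 ± 8.20 in the labelled combination. It was higher in the combination (log2 1.1, adjusted p = 0.00324; 0.161 in the plastid-poor libraries alone), whereas nrp1 nrp2 did not pass (0.85, adjusted p = 0.0524; 0.011 with the library type block and 0.713 in the plastid-poor libraries). The NAP1-related pair, AT1G74560 and AT1G18800, and FYPP1 (AT1G50370) passed in none of the 15 comparisons.

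**Figure D2:**
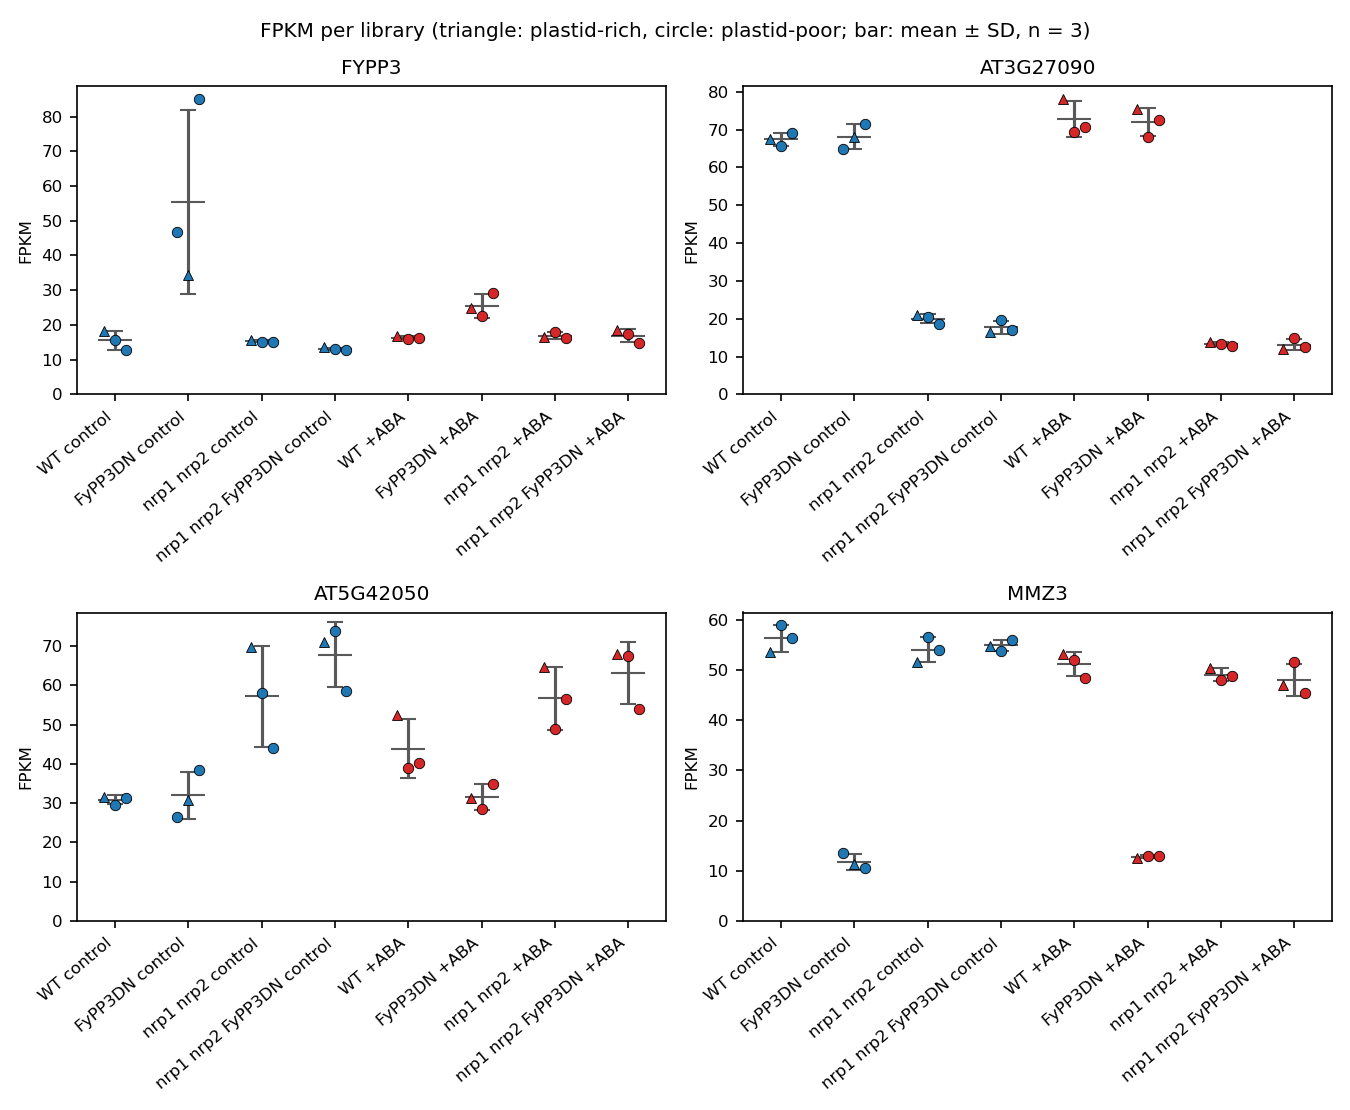
FPKM of FYPP3, AT3G27090, AT5G42050 and MMZ3 in each library by group, with triangles for plastid-rich and circles for plastid-poor libraries and bars for the mean and SD (n = 3). FYPP3 is high and MMZ3 low in FyPP3DN, and neither is so in the libraries labelled nrp1 nrp2 FyPP3DN.

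In WT, ABA raised most of the ABA-responsive genes. The lipid transfer protein gene LTP4 rose from 0.287 ± 0.249 to 131 ± 41.6 FPKM (log2 6.65 ± 0.27 SE, adjusted p = 3.2e-12), and its tandem neighbour LTP3 by a log2 of 4.83. KIN1 and COR15A, which encode small protective proteins of cold and drought, rose by 6.13 ± 0.25 (0.927 to 136 FPKM, adjusted p = 3.2e-12) and 5.70 ± 0.33, and LEA7, a late embryogenesis abundant gene, by 4.61 ± 0.53. Since KIN1 and KIN2 (3.24), and LTP3 and LTP4, are close relatives, their reads may not be fully separated. Of 26 ABA-responsive genes, 23 rose (25 adjusted over the list alone; camera adjusted p = 0.000886). In the other direction, the ABA receptor genes PYL6 (-3.53 ± 0.18, 19.2 to 0.747 FPKM), PYL5 (-2.33 ± 0.18) and PYL4 (-1.64 ± 0.10) fell, as did the glucosinolate gene IGMT1 (-2.53), the receptor kinase gene CRK30 (-2.22) and the gibberellin-regulated GASA5 (-2.20).

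In WT, 7 of 8 clade A PP2C phosphatase genes, which repress ABA signalling, rose (8 adjusted over the list alone; camera adjusted p = 0.000979), among them HAI1 (2.78), HAI2 (2.17) and PP2CA (1.96). 4 of 9 ABA receptor genes fell (5 adjusted over the list alone; 0.00038). 5 of 10 genes of ABA metabolism rose (6 adjusted over the list alone; 0.039, and 0.104 with the library type block and 0.171 in the plastid-poor libraries, in which the PP2C list did not pass either, at 0.0578), both of catabolism (CYP707A1 2.78, CYP707A4 0.72) and of synthesis (NCED3 1.41). Seed maturation genes rose in 6 of 9 cases (7 adjusted over the list alone), with OLEO2 at 2.56, LEA4-2 at 2.24 and EM6 at 1.79, but the list did not pass (adjusted p = 0.146).

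Other lists did not pass in WT (camera adjusted p of at least 0.146), although single members did. Among auxin genes, IAA26 (-0.39) was the only one called of 23 Aux/IAA genes and SAUR9 (-0.98) of 20 SAUR genes, none of 6 GH3 genes, 18 auxin transport genes or 12 auxin receptors and ARFs was called, and CYP79B2 (1.56) and CYP79B3 (0.76), which also make indole glucosinolates, rose among 11 auxin synthesis genes (3 adjusted over the list alone). Over the list alone, the other auxin counts were the same. The library type block added SAUR62 (-0.64, adjusted p = 0.0206), SAUR26 (-0.74, 0.0399), IAA2 (-0.54, 0.0465) and TAA1 (-0.44, 0.0435), which were not called in the pooled fit (0.192 to 0.325). Of 20 cell wall expansion genes, XTH19 (1.63) rose and EXPA1 (-1.41) and XTH4 (-0.62) fell, the same over the list alone. Jasmonate genes rose in 5 of 12 cases (VSP2 3.57, LOX2 1.95, AOS 1.21) and fell in 1 (5 and 2 adjusted over the list alone). 5 of 12 flavonoid genes rose (also 5 over the list alone), including PAP1 (1.51) and DFR (1.48), and 3 of 11 heat shock genes (5 over the list alone), led by HSP18.2 (2.67) and HSP22.0 (2.00). The cytokinin-induced ARR6 (-0.69) and ARR5 (-0.57) fell among 9 type-A ARR genes (3 over the list alone). TSO2 (0.41) rose among 21 cell cycle genes and PAD4 (-0.39) fell among 13 salicylic acid and immunity genes, with the same counts over the list alone. None of 25 photosynthesis, 8 root hair, 11 root tissue, 6 stomatal lineage, 9 clock or 9 PP6 and PP2A genes passed (over the list alone, 1 clock gene fell).

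In total, 871 genes rose and 631 fell with ABA in WT, beside 1186 and 981 with the library type block and 522 and 484 in the plastid-poor libraries. Without WT control replicate 3 the total of 1502 became 944, and without WT +ABA replicate 1 it became 998. SAUR9, CYP79B3, XTH4, TSO2, PAD4 and ARR5 did not pass in the plastid-poor libraries. Without 1 of the 6 libraries, the calls of ARR5, CYP79B3, IAA26, PAD4, TSO2 and XTH4 ended for at least 1 choice of library, and each of the 6 ended at least 1 of them, with adjusted p-values of up to 0.244.

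In nrp1 nrp2, LTP4 (6.18), KIN1 (5.58) and COR15A (4.80) rose most among genes named by the rule, and PYL6 (-3.38), the auxin-induced root gene AIR1 (-2.62) and the nitrate transporter gene NRT1.5 (-2.56) fell. 22 of 26 ABA-responsive genes (25 adjusted over the list alone), 6 of 8 PP2C genes (8) and 5 of 10 ABA metabolism genes (6) rose and 4 of 9 receptor genes (6) fell. Jasmonate genes (4 of 12 up, 6 over the list alone; camera adjusted p = 0.0131) and type-A ARR genes (5 of 9 down, 5 over the list alone; 0.0131) also passed in nrp1 nrp2; whether these lists respond differently from WT was tested by the difference of the responses, in which no list passed. The lists of ABA metabolism and type-A ARR genes did not pass in the plastid-poor libraries (0.0828 each). The counts were 613 up and 560 down, beside 858 and 889 with the library type block and 404 and 272 in the plastid-poor libraries, in which AIR1 did not pass. AIR1 also did not pass without nrp1 nrp2 +ABA replicate 1 or 3 or nrp1 nrp2 control replicate 3 (adjusted p up to 0.0759).

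In FyPP3DN, LTP4 rose by 5.22, COR15A by 4.39 and KIN1 by 4.33, and PYL6 (-3.51), IGMT1 (-2.51) and AIR1 (-2.50) fell. FYPP3 itself fell with ABA (-0.99 ± 0.20, adjusted p = 0.00402). 18 of 26 ABA-responsive genes (23 adjusted over the list alone) and 8 of 8 PP2C genes (8) rose, and 4 of 9 receptor genes (6) fell, and these 3 lists passed (camera adjusted p of 0.00275, 0.00126 and 0.000127); in the plastid-poor libraries the receptor list alone did (0.00433), and the other 2 were at 0.129. The counts were 569 up and 592 down, beside 978 and 975 with the library type block and 367 and 457 in the plastid-poor libraries. The total of 1161 became 727 without FyPP3DN control replicate 1, 679 without FyPP3DN +ABA replicate 1 and 712 without FyPP3DN +ABA replicate 2. AIR1 did not pass without replicate 1 or 2 with ABA or replicate 1 or 3 of the control (adjusted p up to 0.0864).

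In the libraries labelled nrp1 nrp2 FyPP3DN, LTP4 (6.03), KIN1 (5.79) and COR15A (5.78) rose and PYL6 (-3.31), the asparagine synthetase gene ASN1 (-2.56) and IGMT1 (-2.53) fell. 23 of 26 ABA-responsive genes (25 adjusted over the list alone) and 8 of 8 PP2C genes (8) rose and 4 of 9 receptor genes (5) fell, and these 3 lists passed, whereas in the plastid-poor libraries the receptor list alone did (0.00767), and the other 2 were at 0.0594. AT3G27090 fell with ABA both here (-0.41) and in nrp1 nrp2 (-0.56). The counts were 1326 up and 901 down, beside 1987 and 1364 with the library type block and 707 and 526 in the plastid-poor libraries; they were 1174 and 1196 with median-of-ratios scaling and 1113 and 1189 with quantile normalization, so the excess of rises is lost there. Without nrp1 nrp2 FyPP3DN +ABA replicate 1 the total of 2227 became 1426. With a preset correlation of 0.01, 95 of the 360 list tests over all comparisons passed, of which 16 passed with an estimated correlation, all 16 in the 4 ABA responses.

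**Figure D3:**
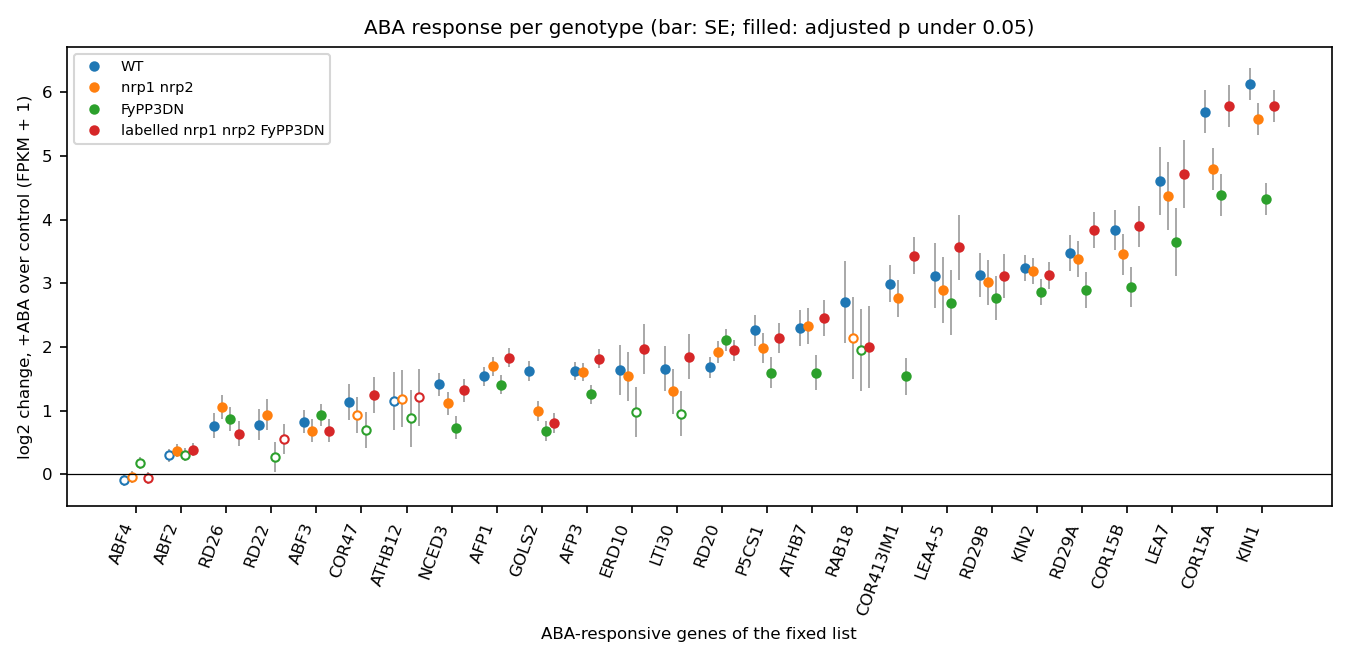
Log2 change with ABA (FPKM + 1) of the 26 ABA-responsive genes in each genotype, with bars for the SE and filled symbols for an adjusted p under 0.05. KIN1 and COR15A are among the largest rises in all 4 genotypes.

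Of the genes called in WT, 517 of 871 rose and 355 of 631 fell in nrp1 nrp2 too, 339 and 292 did so in FyPP3DN, and 754 and 503 in the libraries labelled nrp1 nrp2 FyPP3DN. 503 genes were called in the same direction in all 4 genotypes, 279 up and 224 down. In the pair of WT and FyPP3DN, 1 gene was called in opposite directions.

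Without ABA, nrp1 nrp2 differed from WT in few genes. PR2, a marker of salicylic acid responses, was at 0.233 ± 0.186 FPKM in nrp1 nrp2 and 6.76 ± 5.60 in WT (log2 -2.44 ± 0.40, adjusted p = 0.0114), the regulator gene WRKY70 was lower by a log2 of -1.18 (0.0477), and AIG1, induced by bacterial effectors, by -2.36 (0.0118). PCR1 (-2.72 ± 0.39, adjusted p = 0.00229) and the jasmonate-induced TAT3 (-2.15, 0.0184) were also lower. ERD5, which encodes a proline dehydrogenase, was higher (0.74 ± 0.12, 113 against 67.8 FPKM, 0.0118). Of 13 salicylic acid and immunity genes, 2 were lower (4 adjusted over the list alone), of 12 jasmonate genes 1 (1), and of 21 cell cycle genes 1 was higher over the list alone. No list passed camera (lowest adjusted p = 0.122). The levels in WT varied between its libraries: PR2 ranged from 3.38 to 13.2 FPKM.

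In total 3 genes were higher and 15 lower, beside 13 and 28 with the library type block and 2 and 7 in the plastid-poor libraries, in which ERD5, PR2, WRKY70, AIG1, PCR1 and TAT3 no longer passed. Besides ERD5, the genes higher were AT3G05170 and AT3G44006, named after their values were seen. Without WT control replicate 1 the total of 18 became 9, and without nrp1 nrp2 control replicate 3 it became 10. Without 1 library, ERD5, PR2, AIG1, TAT3 and WRKY70 lost their call for at least 1 choice among WT control replicates 1 and 2 and the 3 nrp1 nrp2 control replicates (adjusted p up to 0.381), and all 5 did so without WT control replicate 1.

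FyPP3DN differed from WT in more genes without ABA than nrp1 nrp2 did in the pooled fit (113 beside 18). In a fit of only the groups compared, these counts were 9 and 5. OSM34, which encodes an osmotin, was at 81.1 ± 38.1 FPKM against 5.16 ± 2.41 (log2 3.70 ± 0.40, adjusted p = 4.8e-05), the defensin gene PDF2.1 was higher by 2.40 (0.000139), the glucosinolate gene IGMT2 by 2.51 (6.0e-05), the glutathione transferase gene GSTF7 by 2.26 (0.0321) and ICL, an enzyme gene of the glyoxylate cycle, by 2.86 (0.0246; 25.3 ± 26.7 FPKM). FYPP3 was higher by 1.68 ± 0.20 (0.000139). MMZ3, which encodes a ubiquitin-conjugating enzyme variant, was at 11.8 ± 1.53 against 56.3 ± 2.71 FPKM (-2.17 ± 0.08, 8.9e-13). PCR1 (-2.59), AIG1 (-2.53), PR2 (-2.34), TAT3 (-2.27), PR1 (-2.19) and WRKY70 (-1.19) were lower, as were PRR7 (-0.66) of the clock and CYP707A2 (-0.53), while GOLS2 (0.74) was higher.

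Of 13 salicylic acid and immunity genes, 3 were lower in FyPP3DN without ABA (7 adjusted over the list alone), and of 25 photosynthesis genes none was called, but 7 were lower over the list alone. Likewise, 3 of 9 seed maturation genes and 1 of 21 cell cycle genes were higher and 2 of 9 clock genes lower. No list passed camera (lowest adjusted p = 0.317). 48 genes were higher and 65 lower, beside 202 and 257 with the library type block and 26 and 17 in the plastid-poor libraries, in which PCR1, AIG1, PR2, TAT3, PR1, WRKY70, ICL, GSTF7, PRR7, CYP707A2 and GOLS2 no longer passed. The total of 113 became 64, 47 and 54 without WT control replicates 1, 2 and 3, 49 without FyPP3DN control replicate 1 and 231 without FyPP3DN control replicate 2. CYP707A2, GOLS2, GSTF7, ICL, PR1, PRR7 and WRKY70 lost their call without 1 library, and each of the 6 libraries ended at least 1 of them (adjusted p up to 0.189).

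Of the 18 genes called in nrp1 nrp2 without ABA, 12 were called in the same direction in FyPP3DN, including PCR1, AIG1, TAT3, WRKY70 and PR2. None of these named genes passed in the plastid-poor libraries in either comparison. The 12 also include AT2G01422, AT2G06995, AT3G05170 and AT3G05955, named after their values were seen. They were called against WT in every other genotype, without and with ABA, so they do not show an effect particular to nrp1 nrp2 and FyPP3DN. Both comparisons share the WT libraries. Across all genes, the correlation of the differences was 0.559 and their covariance 0.0308, beside means of 0.499 and 0.0132 in 20 simulations of unchanged groups that share libraries in the same way.

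The libraries labelled nrp1 nrp2 FyPP3DN differed little from WT without ABA. GASA5 was lower (log2 -1.54 ± 0.18, 1.53 against 6.44 FPKM, adjusted p = 0.000163), as were the alanine aminotransferase gene ALAAT2 (-0.77, 0.0116) and the wall-associated kinase gene WAK2 (-0.51, 0.0463). In total 7 genes were higher and 9 lower, beside 9 and 10 with the library type block and 2 and 4 in the plastid-poor libraries, in which GASA5, ALAAT2 and WAK2 no longer passed. No list passed (lowest adjusted p = 0.301), and over the list alone 1 of 20 cell wall expansion genes and 1 of 12 jasmonate genes were lower. Of the 16 genes, 7 were also called in nrp1 nrp2 in the same direction, AT3G27090 among them; the correlation across all genes was 0.312 and the covariance 0.0122, beside 0.497 and 0.0131 in simulated unchanged groups. Without WT control replicate 2 the total became 10. WAK2 lost its call without any 1 of the 6 libraries (adjusted p up to 0.495), and ALAAT2 without WT control replicate 2 or 3 or replicate 1 or 3 of the labelled combination.

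Against nrp1 nrp2, the same libraries had higher ASN1 (log2 1.84 ± 0.31, 16.5 against 3.78 FPKM, adjusted p = 0.0229), the aldolase gene FBA5 (0.97, 332 against 169 FPKM, 0.00357) and HOL2 (0.93, 0.01), and lower GASA5 (-1.45, 0.00243) and ALAAT2 (-0.96, 0.00305). Of 21 cell cycle genes none was called, but 10 were lower over the list alone, as were 2 of 20 cell wall expansion genes, while 3 of 13 salicylic acid and immunity genes and 1 of 9 clock genes were higher. No list passed camera (lowest adjusted p = 0.0752). In total 7 genes were higher and 2 lower. The library type block gave 112 and 61 and the replicate block, in which the replicate numbers are paired, 31 and 10. The plastid-poor libraries gave 0 genes with limma (2197 at an unadjusted p under 0.05, beside 2202 in all libraries). With median-of-ratios scaling 18 were higher and 2 lower, and with quantile normalization 21 and 2. The total of 9 became 3 without nrp1 nrp2 control replicate 3 and 5 without nrp1 nrp2 FyPP3DN control replicate 3. ASN1 did not pass without replicate 2 or 3 of nrp1 nrp2 or replicate 1 or 3 of the labelled combination, nor HOL2 without replicate 1 or 3 of nrp1 nrp2 or replicate 3 of the combination (adjusted p up to 0.218).

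With ABA, nrp1 nrp2 again differed from WT in few genes. ERD5 was higher (log2 0.79 ± 0.12, 54.0 against 31.0 FPKM, adjusted p = 0.00672), and so was CYP707A2, which encodes an enzyme that degrades ABA (0.65 ± 0.12, 11.0 against 6.72 FPKM, 0.0297). CYP707A2 was the only one called of 10 ABA metabolism genes (1 over the list alone). None of 26 ABA-responsive genes and none of 8 PP2C genes was called, also over the list alone. Adjusted over the list alone, 4 of 11 heat shock genes, 3 of 9 seed maturation genes and 2 of 13 salicylic acid and immunity genes were lower and 1 of 21 cell cycle genes was higher. No list passed camera (lowest adjusted p = 0.247). 5 genes were higher and 8 lower, beside 7 and 9 with the library type block and 2 and 5 in the plastid-poor libraries, in which ERD5 and CYP707A2 no longer passed. ERD5 did not pass without WT +ABA replicate 1 or 3 or nrp1 nrp2 +ABA replicate 2 or 3, nor CYP707A2 without WT +ABA replicate 1 or 2 or any 1 of the nrp1 nrp2 +ABA libraries (adjusted p up to 0.31). The other genes higher, named after their values were seen, were AT3G05170, AT3G44006 and RPN12b.

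FyPP3DN with ABA had mostly lower genes against WT with ABA. MLP328 and MLP34, of the major latex protein family, were lower by -2.29 ± 0.34 (115 ± 50.3 against 538 ± 104 FPKM, adjusted p = 0.00181) and -2.01 (0.00398), and GSTU25 by -2.13 (0.0252). ICL (2.46, 0.0459), the extensin gene EXT4 (1.03, 0.0342) and BT2 (0.89, 0.0328) were higher. Of the genes already named, HSP18.2 (-1.87 ± 0.20, adjusted p = 4.1e-05), HSP22.0 (-1.23), VSP2 (-1.83), LTP4 (-1.34), PCR1 (-1.95), PR2 (-2.19) and MMZ3 (-1.92) were lower and HKL1 (0.42) was higher. Of 12 jasmonate genes 2 were lower (7 adjusted over the list alone), of 26 ABA-responsive genes 1 (7) and of 25 photosynthesis genes 0 (9, and 1 higher), while 8 of 9 seed maturation genes were higher over the list alone and 0 over all genes. Of 11 heat shock genes 2 were lower (3) and of 13 salicylic acid and immunity genes 1 (3). Adjusted over the list alone, 2 of 6 GH3 genes and 2 of 21 cell cycle genes were higher, and 1 of 9 ABA receptor genes was higher and 1 lower. No list passed camera (lowest adjusted p = 0.131).

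In total 24 genes were higher and 150 lower in FyPP3DN with ABA, beside 67 and 296 with the library type block and 3 and 37 in the plastid-poor libraries. In the latter, ICL, EXT4, BT2, HKL1, VSP2, LTP4, PCR1 and PR2 no longer passed. The total of 174 became 76, 111 and 73 without WT +ABA replicates 1, 2 and 3, and 73 and 104 without FyPP3DN +ABA replicates 1 and 2. The same 8 genes and GSTU25 lost their call without 1 library, and each of the 6 libraries ended at least 1 of them (adjusted p up to 0.229). Of the 174 genes, 4 were called in the same direction in nrp1 nrp2 with ABA (AT2G01422, AT2G06995, AT3G05170 and AT3G05955, named after their values were seen); the correlation across all genes was 0.365 and the covariance 0.0169, beside 0.502 and 0.0133 in simulated unchanged groups.

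With ABA, the libraries labelled nrp1 nrp2 FyPP3DN had higher HKL1, a hexokinase-like gene (log2 0.61 ± 0.10, adjusted p = 0.00749), and lower ALAAT2 (-0.75, 0.0165) and SAPX, which encodes a chloroplast ascorbate peroxidase (-0.69, 0.0116), than WT. GOLS2 was lower (-0.88 ± 0.16, 0.0245). In total 4 genes were higher and 13 lower (7 and 12 with quantile normalization), beside 8 and 17 with the library type block and 2 and 5 in the plastid-poor libraries, in which HKL1, ALAAT2, SAPX and GOLS2 no longer passed. The other 3 genes higher were AT3G05170, AT3G44006 and RPN12b, named after their values were seen. The total of 17 became 10 without nrp1 nrp2 FyPP3DN +ABA replicate 1 or replicate 2. Without 1 library, HKL1 (replicate 2 of the labelled combination), ALAAT2 and SAPX (its replicate 1 or 2, or WT +ABA replicate 2) and GOLS2 (its replicate 1 or 3, or WT +ABA replicate 1 or 2) did not pass (adjusted p up to 0.204). No list passed (lowest adjusted p = 0.172). Over the list alone, 4 of 9 seed maturation genes, 1 of 26 ABA-responsive genes and 1 of 13 salicylic acid and immunity genes were lower, and 1 gene each of ABA metabolism, Aux/IAA and GH3 was higher. 10 of these 17 genes were called in the same direction in nrp1 nrp2, with a correlation across all genes of 0.564 and a covariance of 0.0165, beside 0.5 and 0.0132 in simulated unchanged groups.

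Against nrp1 nrp2 with ABA, the libraries labelled nrp1 nrp2 FyPP3DN differed in 2 genes: HKL1 was higher (log2 0.63 ± 0.10, 14.2 ± 0.972 against 8.85 ± 0.552 FPKM, adjusted p = 0.0279) and ALAAT2 lower (-0.89 ± 0.13, 3.71 ± 0.672 against 7.67 ± 0.269 FPKM, 0.0178). No list passed (lowest adjusted p = 0.871), and over the list alone 1 of 20 SAUR genes and 1 of 12 jasmonate genes were higher. With the library type block 1 gene was higher and 1 lower, and in the plastid-poor libraries limma called 0 genes (559 at an unadjusted p under 0.05, beside 643 in all libraries). The total of 2 became 0 without nrp1 nrp2 +ABA replicate 1 or 2 or without nrp1 nrp2 FyPP3DN +ABA replicate 1 or 2, and 1 without replicate 3 of either group. HKL1 did not pass without any 1 of the 6 libraries, nor ALAAT2 without any of the 6 except replicate 3 of the labelled combination (adjusted p up to 0.421).

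None of the 13 genes by which nrp1 nrp2 differed from WT with ABA was called in the opposite direction in that last comparison, as a return toward WT would require. The values had the opposite sign in 8 of the 13, and 10 of the 13 were called in the same direction against WT in the labelled combination. These 10 include AT3G27090, the gene whose fall marks the mutant, which a return could not involve. AT2G01422, AT2G06995, AT3G05170 and AT3G05955, also among them, were called the same way in FyPP3DN against WT, so no return through FyPP3DN was likely. ERD5 (-0.48), CYP707A2 (-0.24) and AT5G41380 (0.34) had values toward WT that did not pass, and the combination did not pass against WT in them. Since the comparisons share the nrp1 nrp2 libraries, opposite signs are common by chance: over all genes they made up 68.5%, beside 66.7% in simulated unchanged groups. FYPP3 was not raised in these libraries, so these counts do not measure what FyPP3DN does in nrp1 nrp2.

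The ABA response of nrp1 nrp2 did not differ from that of WT in any gene with limma (0 genes, 353 at an unadjusted p under 0.05; also 0 with the library type block and in the plastid-poor libraries), and no list passed (lowest adjusted p = 0.351). Over the list alone, 4 of 9 seed maturation genes had a lower response and 2 of 13 salicylic acid and immunity genes and 1 of 12 jasmonate genes a higher one. The response of the libraries labelled nrp1 nrp2 FyPP3DN did not differ from that of nrp1 nrp2 in any gene either (0 genes with limma, 989 unadjusted), and no list passed (0.504). Over the list alone, 1 cell wall expansion gene and 1 heat shock gene had a higher response and 1 salicylic acid and immunity gene a lower one.

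The ABA response of FyPP3DN differed from that of WT in 28 genes, 26 of them with a lower response. OSM34 rose with ABA in WT from 5.16 ± 2.41 to 99.2 ± 11.1 FPKM, and was at 81.1 ± 38.1 without and 72.3 ± 46.1 with ABA in FyPP3DN (difference of responses -4.33 ± 0.57, adjusted p = 0.00191). The differences were -2.51 for PDF2.1 (0.0117), -3.26 for GSTU25 (0.0458), -2.16 for HSP18.2 (0.00191), -1.91 for LTP3 (0.031) and -1.81 for KIN1 (0.0465). BT1 (1.31 ± 0.26, 0.0434) and PDX1.1, a vitamin B6 synthesis gene (0.69 ± 0.13, 0.0348), had the higher response. Of the 26 genes, 24 rose with ABA in WT, 7 were already called higher in FyPP3DN without ABA, and 19 were called lower in FyPP3DN with ABA. No list passed camera (lowest adjusted p = 0.644). Over the list alone, 3 of 26 ABA-responsive genes, 3 of 11 heat shock genes, 3 of 12 jasmonate genes and 1 of 9 PP6 and PP2A genes had a lower response, and 1 ABA metabolism gene and 1 clock gene a higher one.

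The library type block, which leaves the differences as they are and lowers their spread, gave 84 genes, 15 higher and 69 lower, and in the plastid-poor libraries 6 of the 28 kept their call (1 gene higher and 7 lower in total), with all 28 in the same direction; of the genes named here, only GSTU25 did. The total became 14 and 13 without WT control replicates 1 and 3, 110 and 9 without FyPP3DN control replicates 2 and 3, 12 and 17 without WT +ABA replicates 2 and 3, and 15 without FyPP3DN +ABA replicate 1 or 2. BT1, PDX1.1, GSTU25, KIN1, LTP3 and PDF2.1 lost their call without 1 library, PDF2.1 without FyPP3DN control replicate 3 alone (0.0519) and the others for several of the 12 (adjusted p up to 0.164).

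**Figure D4:**
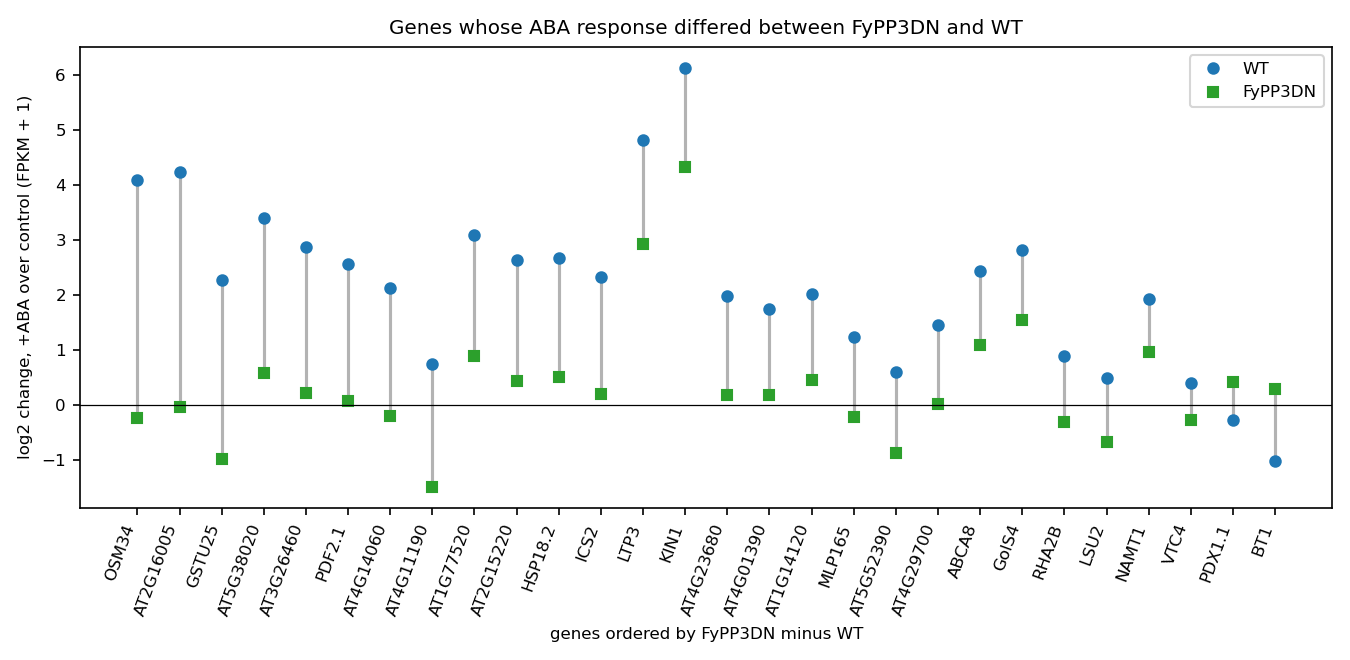
Log2 change with ABA (FPKM + 1) in WT (circles) and in FyPP3DN (squares) of the 28 genes whose response differed between them, ordered by the difference. OSM34 has the largest difference, at -4.33.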

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

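In this part, the contrast of the FyPP3DN effect between backgrounds with its splits, and the tests of FyPP3DN activity, of swapped libraries, of scaling and of the library type, were chosen only after the results were seen; the prediction for the score of the ABA response was written before its value was seen, but after the 28 genes were.

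The ABA response of FyPP3DN differed from that of WT by a test of the difference itself in 28 genes. The difference was positive for BT1 (log2 1.31) and PDX1.1 (0.69) and negative for OSM34 (-4.33), GSTU25 (-3.26), PDF2.1 (-2.51), HSP18.2 (-2.16), LTP3 (-1.91) and KIN1 (-1.81). The count became 14 and 13 without WT control replicates 1 and 3, 110 and 9 without FyPP3DN control replicates 2 and 3, 12 and 17 without WT +ABA replicates 2 and 3, and 15 without FyPP3DN +ABA replicate 1 or 2. Of the 8 genes, OSM34 and HSP18.2 kept their call without any 1 library, and PDF2.1 lost it without FyPP3DN control replicate 3 (adjusted p = 0.0519); the other 5 lost it for several of the 12 libraries (up to 0.164). With median-of-ratios scaling 0 genes had a higher response and 29 a lower one with limma, and with quantile normalization 5 and 27.

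Of 100 drawn splits of these 12 libraries that kept the treatments apart, 3 gave at least 28 genes, the real one included, a share under 0.05 for the pooled fit. The splits exchange genotypes within a treatment. Their share therefore bears on whether the genotypes are interchangeable, and it does not exclude chance for the difference of the responses itself. The highest other count, 93, came from a trade of WT control replicate 2 with FyPP3DN control replicate 2, which puts the plastid-rich libraries of the controls on 1 side. Among the 35 splits with even library types, 1 gave as many, the real one, and the highest other count was 14. With the library type block, 4 of 100 splits gave at least the real 84 genes and the highest other gave 235, when WT +ABA replicates 1 and 3 traded with FyPP3DN +ABA replicates 2 and 3. Among the 35 even splits 2 then did, with 130 as the highest other, a share over 0.05, so for the 84 genes the side of 0.05 depends on which splits are counted. Trades within 1 treatment let part of the genotype difference into the contrast, so these counts do not show another structure of the samples.

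As to the cause of this lower response, in the plastid-poor libraries alone the 28 genes, signed by their direction in all libraries, had a median difference of 1.89 (quartiles 1.34 and 2.55; 1.80 in all libraries), which argues against the plastid-rich libraries as the cause, although 6 of the 28 kept their call with 2 libraries per group and the genes were called partly from these libraries. Over 1326 genes that rose and 901 that fell with ABA in the libraries labelled nrp1 nrp2 FyPP3DN, which are neither WT nor FyPP3DN libraries, the response of FyPP3DN was 0.667 of that of WT (exact permutation p = 0.01, 400 permutations; 0.585 in the plastid-poor and 0.845 in the plastid-rich libraries). The labelled combination shared 754 of the 871 rises and 503 of the 631 falls of WT. Genes that respond only in FyPP3DN are left out of the set, which can lower the ratio. The permutations exchange genotypes within a treatment, so their p bears on whether the genotypes are interchangeable, not on the responses alone. The score was higher in FyPP3DN than in WT without ABA (-0.977 and -1.18) and lower with ABA (-0.015 and 0.26). A weaker ABA response over these genes on average may therefore be part of the difference, as a hypothesis. It falls short for single genes such as AT2G16005 (4.24 in WT and -0.05 in FyPP3DN) and PDF2.1 (2.57 and 0.07), and OLEO2 went the other way (3.48 in FyPP3DN and 2.56 in WT), though its difference did not pass (adjusted p = 0.741); these genes were picked after their values were seen. Whether the dominant-negative FYPP3, another difference of the line or its growth accounts for it was not tested.

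The FyPP3DN effect on FYPP3 differed by a test of the difference itself between the nrp1 nrp2 and the WT background without ABA (log2 -1.90 ± 0.28, adjusted p = 0.00194; -1.54 to -2.18 without any 1 of the 12 libraries). The same test called 760 genes without ABA, 406 with a higher and 354 with a lower difference, and 101 with ABA, 85 and 16. With the library type block there were 2126 genes without ABA, 982 higher and 1144 lower, and 278 with ABA, 235 and 43. In the plastid-poor libraries there were 720, 359 and 361, and 10, 8 and 2. Without ABA the count became 277 without WT control replicate 3, 374 and 1347 (593 higher and 754 lower) without FyPP3DN control replicates 1 and 2, 429 and 280 without nrp1 nrp2 control replicates 2 and 3, and 375 and 436 without nrp1 nrp2 FyPP3DN control replicates 1 and 2. With ABA it became 62 and 52 without WT +ABA replicates 1 and 3, 53, 268 and 60 without nrp1 nrp2 +ABA replicates 1, 2 and 3, and 62 and 47 without nrp1 nrp2 FyPP3DN +ABA replicates 1 and 2. With organelle genes removed there were 382 higher and 418 lower without ABA, so which direction holds more genes depends on the setting there.

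Of 100 drawn splits, 2 gave at least 760 genes without ABA and 2 gave at least 101 with ABA, the real one included each time. Among splits with even library types these were 1 of 39 without ABA, a share under 0.05, and 2 of 35 with ABA, a share over 0.05. For the 101 genes the side of 0.05 therefore depends on which splits are counted. These splits exchange labels within a background, and the contrast was chosen after the values were seen. Their shares do not exclude chance for the difference between backgrounds itself. Without ABA the highest other count, 802, came with uneven library types (WT control replicate 2 traded with FyPP3DN control replicate 2, and nrp1 nrp2 control replicate 1 with nrp1 nrp2 FyPP3DN control replicate 3). The highest other among the even splits was 27, and with the library type block 1 of 100 splits reached the real 2126, with 209 as the highest other. With ABA the highest other count was 398, and with the block 2594 beside the real 278, both when WT +ABA replicate 2 traded with FyPP3DN +ABA replicate 3 and nrp1 nrp2 +ABA replicate 2 with nrp1 nrp2 FyPP3DN +ABA replicate 3. That split is even in library type and calls several times the real count, but it was picked as the highest of those drawn. Without nrp1 nrp2 +ABA replicate 2, which it trades, the real count became 268. Whether that library or a structure that the labels do not give accounts for the split was not tested.

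For the FYPP3 transcript that was not raised in the libraries labelled nrp1 nrp2 FyPP3DN, 3 explanations were tested. The lowest FPKM of AT3G27090 in a library labelled FyPP3DN was 64.9, far above nrp1 nrp2, which argues against a swap of libraries between FyPP3DN and the combination. Other scalings moved the median of all genes by at most 0.0465 between the combination and nrp1 nrp2 without ABA, which argues against the authors' normalization. The 112 genes called in FyPP3DN against WT without ABA, signed by their direction there, had a median of 0.906 in that comparison. In the combination against nrp1 nrp2 it was -0.328, and 19 of 112 moved in the same direction. With ABA the median was 0.296 in FyPP3DN against WT, where 88 of 112 kept their direction, and -0.04 in the combination against nrp1 nrp2. A candidate explanation is that these libraries had no FyPP3DN activity, through another line or a lost or silenced transgene, which the values do not separate; the negative sign without ABA goes beyond what missing activity predicts and stays open.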

How the results depend on the processing

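The library type block and the repeat on plastid-poor libraries, the settings of the FyPP3DN effect between backgrounds, and the genes named after their values were seen were chosen only after the results were seen; the other settings were chosen beforehand. A count is called moved where it differs from the pooled one by over 1.5 times. The cause of a moved count was not tested unless it is named.

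With a fold of at least 2 as a further condition, fewer genes can be called by construction. ABA responses had 517 genes in WT, 431 in nrp1 nrp2, 384 in FyPP3DN and 644 in the labelled combination. FyPP3DN against WT had 53 without and 93 with ABA, the combination against nrp1 nrp2 3 without ABA and 0 with ABA (limma, 643 unadjusted), the combination against WT with ABA 9, and the FyPP3DN effect between backgrounds 212 without ABA. With a mean FPKM of at least 5, which leaves fewer genes to test, ABA responses had 885, 669, 667 and 1400 genes in the same order. nrp1 nrp2 against WT had 4 without and 4 with ABA, FyPP3DN against WT 53 and 91, the combination against WT 5 and 6, and the FyPP3DN effect between backgrounds 59 with ABA.

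A pseudocount of 0.1 gave 11 genes for nrp1 nrp2 against WT without ABA and 11 for the combination against WT with ABA, and no filter gave 20 for nrp1 nrp2 against WT with ABA. For the combination against nrp1 nrp2 without ABA, median-of-ratios scaling gave 20 and quantile normalization 23. The replicate block, in which replicate numbers are paired, gave 41 there and 191 for FyPP3DN against WT without ABA. Other counts under these settings, and all counts with organelle genes removed or without an intensity trend, stayed within 1.5 times. Scaling moved the median of all genes by at most 0.0863. It changed the balance of directions in the ABA response of the combination (1174 up and 1196 down with median-of-ratios scaling, 1113 and 1189 with quantile normalization), in the ABA response of nrp1 nrp2 (564 up and 605 down with organelle genes removed) and in the FyPP3DN effect between backgrounds without ABA (540 and 275 with quantile normalization, 382 and 418 with organelle genes removed).

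The library type block raised the ABA response to 1953 genes in FyPP3DN and 3351 in the combination, nrp1 nrp2 against WT without ABA to 41, FyPP3DN against WT to 459 without and 363 with ABA, the combination against nrp1 nrp2 without ABA to 173, the difference of the ABA response between FyPP3DN and WT to 84, and the FyPP3DN effect between backgrounds to 2126 without and 278 with ABA. The block removes the spread between library types and, with types balanced over the groups, leaves every log2 difference as it is, so by construction it can hardly end a call. The plastid-poor libraries alone, with 2 per group, gave 676 genes for ABA in nrp1 nrp2 and 1233 in the combination, 9 and 7 for nrp1 nrp2 against WT without and with ABA, 43 and 40 for FyPP3DN, 6 and 7 for the combination, 0 and 0 for the combination against nrp1 nrp2 (limma, 2197 and 559 unadjusted), 8 for the difference between FyPP3DN and WT, and 10 for the FyPP3DN effect between backgrounds with ABA. Fewer samples lower these counts by construction.

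A fit of only the groups compared, with fewer samples to estimate the spread, gave 514 genes for ABA in nrp1 nrp2, 236 for ABA in FyPP3DN, 5 and 5 for nrp1 nrp2 against WT without and with ABA, 9 and 81 for FyPP3DN, 6 and 5 for the combination, 1 and 0 for the combination against nrp1 nrp2 (limma, 478 unadjusted with ABA), and 6 for the difference between FyPP3DN and WT. For ABA in WT and in the combination, with as many samples, it gave 1228 and 2282 genes, beside 1502 and 2227 in the pooled fit. Fewer samples alone therefore do not account for the fall to 236 in FyPP3DN. The pooled calls in FyPP3DN rest on a spread shared with the other groups. This fit was not run for the FyPP3DN effect between backgrounds. Of 360 list tests, 16 passed with camera and an estimated correlation and 15 with the library type block; 95 passed with a preset correlation, 36 with directional fry, 52 with mixed fry, and 8 in the plastid-poor libraries.

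Leaving out 1 library gave ABA responses of 944 to 1287 genes in WT, 829 to 1085 in nrp1 nrp2, 679 to 1571 in FyPP3DN and 1426 to 1937 in the combination. Without ABA it gave 9 to 17 for nrp1 nrp2 against WT, 47 to 231 for FyPP3DN, 10 to 15 for the combination and 3 to 11 for the combination against nrp1 nrp2. With ABA these were 9 to 13, 73 to 192, 10 to 15 and, for nrp1 nrp2 FyPP3DN against nrp1 nrp2 with ABA, 0 to 1 (limma; 362 to 1103 unadjusted where 0). The difference of the ABA response between FyPP3DN and WT had 9 to 110 genes, and the FyPP3DN effect between backgrounds 277 to 1347 without and 47 to 268 with ABA. The difference of the ABA response between nrp1 nrp2 and WT, that between the combination and nrp1 nrp2, and the return of nrp1 nrp2 changes in the combination stayed at 0 to 0 genes without any 1 library and 0 under every other setting run (limma; 353 and 989 unadjusted for the differences, and opposite signs in 8 of 13 genes for the return, in the pooled fit). Each library that moved a count by over 1.5 times is named beside it. A group left with 2 libraries borrows its spread from the other groups.

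Of 128 values of named genes called in all libraries, none reversed under any setting. With no filter, a mean FPKM of at least 5, no intensity trend, either block or only the groups compared, no reversal could arise. Those settings leave every log2 difference as it is. The number that lost the call was 12 with a pseudocount of 0.1, 9 with no filter, 4 of 93 with a mean FPKM of at least 5, 8 with median-of-ratios scaling, 2 with quantile normalization, 1 with organelle genes removed, 0 without an intensity trend, 3 with the replicate block, 0 with the library type block, 57 in the plastid-poor libraries and 54 of 127 in a fit of only the groups compared. Without 1 library, 49 of the 128 lost the call at least once. The values not called that were followed, 82 in number, are those of FYPP3, FYPP1, AT3G27090, AT5G42050, AT1G74560 and AT1G18800. Of these, 1 passed with quantile normalization, 1 with organelle genes removed, 1 with the replicate block and 2 with the library type block. The auxin genes that the library type block added in the ABA response of WT are not among the 82. Depth, at 16.6 to 29.1 M fragments, limits genes of low FPKM, which rest on few fragments; the pseudocount and the filters act on these.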

Other observations

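In this part, the tests of greener tissue and of GC content, the correlation between the effects labelled FyPP3DN, the score of the ABA response in nrp1 nrp2, and the genes that differ between lines were chosen only after the results were seen. The predictions for A-rich transcripts, for the splits of planned comparisons and for the score in FyPP3DN were written before the values they concern were seen.

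For the 1 library of each group that was rich in plastid-encoded transcripts, 3 explanations were weighed, and the design gives no biological one. Nuclear photosynthesis genes had a median log2 difference of -0.194 between plastid-rich and plastid-poor libraries, which argues against more green tissue. 832 nuclear genes with a GC content of at most 36.7%, the median of plastid-encoded genes, had a median of 0.214 (0.152 to 0.326 over the groups) beside 3.68 (2.97 to 4.97) for 103 plastid-encoded genes, which argues against GC content as the whole cause, although the difference fell with GC content across nuclear genes (rho -0.439). RNA selection that captured A-rich transcripts stays open: the rho of the difference with the highest A share in a window of the transcript was 0.126 (-0.00233 to 0.204 over the groups; 0.0672 for T) and, given transcript length, 0.21 (0.132 for T), where a rho of at least 0.2, and 0.1 above that of T, was predicted and at most 0.05 set against it. Mitochondrial genes had a median of 1.14 and small nucleolar RNA genes 0.27, beside -0.06 for protein-coding genes. The extract protocol names poly(A) selection or rRNA removal without saying which library had which. Whether the preparation differed between the library types was therefore not tested.

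With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In the ABA responses the real count was 1502 in WT, 1173 in nrp1 nrp2, 1161 in FyPP3DN and 2227 in the labelled combination, and 1 of 10 splits, the real one, gave as many; the highest other was 22 in FyPP3DN and 0 in the other 3 (limma). Without ABA the real counts were 18 for nrp1 nrp2 against WT, 113 for FyPP3DN, 16 for the combination and 9 for the combination against nrp1 nrp2, and with ABA 13, 174, 17 and 2, each in 1 of 10 splits, with 0 as the highest other. Under the library type block, the 2 genes of the combination against nrp1 nrp2 with ABA were exceeded by 6 when nrp1 nrp2 +ABA replicate 2 traded with nrp1 nrp2 FyPP3DN +ABA replicate 3. For the differences of the ABA response of nrp1 nrp2 from WT and of the combination from nrp1 nrp2, the real count was 0 (353 and 989 unadjusted), so 100 of 100 splits give as many by construction, which decides nothing; the highest others were 1 and 2. With the block, the same trade of nrp1 nrp2 +ABA replicate 2 gave 343 genes for the latter difference, but a trade within 1 treatment also lets in part of the genotype difference.

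Without ABA, the effect labelled FyPP3DN in the nrp1 nrp2 background ran against that in WT. Across 19500 genes, the 2 sets of differences, which share no libraries, had an r of -0.478 (-0.522 in the plastid-poor libraries), and with ABA an r of -0.186 (0.0528). Among genes picked after their values were seen, the difference between these effects without ABA was negative for ICL (log2 -3.95), OSM34 (-3.44, adjusted p = 0.00241), PDF2.1 (-3.35, 0.000195), IGMT2 (-2.44) and THAS1 (-2.14). It was positive for PCR1 (4.63, 0.000182), PR2 (3.67, 0.00195), AIG1 (3.58), TAT3 (2.80) and ASN1 (2.67). LHB1B1, which encodes a light-harvesting protein, had a difference of 1.83 ± 0.39 (0.0126), from 3043 ± 743 FPKM in WT and 1392 ± 158 in FyPP3DN, and 2118 ± 367 in nrp1 nrp2 and 3532 ± 845 in the labelled combination. No list passed for this contrast (lowest camera adjusted p = 0.149, clock genes, 2 of 9 higher). Single members called higher were 5 of 25 photosynthesis genes, 3 of 13 salicylic acid and immunity genes, 1 of 10 ABA metabolism genes and 1 of 12 jasmonate genes. Called lower were 3 of 21 cell cycle genes, 2 of 20 cell wall expansion genes, 1 of 26 ABA-responsive genes, 1 of 9 seed maturation genes and 1 of 9 PP6 and PP2A genes.

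For 4 genes picked after their values were seen, levels spread widely within groups. Without ABA, mean FPKM in WT, nrp1 nrp2, FyPP3DN and the combination was 6.76, 0.233, 0.35 and 2.38 for PR2, 4.99, 0.26, 0.26 and 3.23 for PR1, 7.60, 0.267, 0.377 and 4.51 for PCR1, and 5.47, 1.81, 1.74 and 3.96 for WRKY70. None of these 4 genes was called in the combination against nrp1 nrp2 without ABA. The salicylic acid and immunity list did not pass for the contrast between the effects labelled FyPP3DN (camera adjusted p = 0.321), although 3 of its 13 genes were called higher.

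On the score of the ABA response, the response was 1.44 in WT, 1.24 in nrp1 nrp2 (ratio 0.862, exact permutation p = 0.045, 400 permutations) and 0.962 in FyPP3DN (0.667, exact permutation p = 0.01). The value for nrp1 nrp2 was 0.819 in the plastid-poor and 0.954 in the plastid-rich libraries. Since the permutations exchange genotypes within a treatment, both p-values bear on whether the genotypes are interchangeable, not on the responses alone. The genes were called in the labelled combination, and those that respond only in another genotype are left out, which can shift the ratios. Limma called 0 genes for the difference between the responses of nrp1 nrp2 and WT.

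Several genes, picked after their values were seen, separate the lines in every library. MMZ3 (chromosome 2, 15142653 to 15144221) was at 10.45 to 13.4 FPKM in the 6 FyPP3DN libraries and 45.4 to 58.9 in the other 18, with 45.4 to 56.0 in the labelled combination. AT4G05275 had means of 9.09 and 6.55 without and with ABA in FyPP3DN, was listed at 0 in all 6 libraries of the combination, and had means of at most 0.07 elsewhere. AT3G05955 had means of 15.0 and 11.0 in WT and of at most 1.01 in the other genotypes. Its single libraries were at 10.2 or more in WT and at 1.31 or less elsewhere. AT3G05170 had means of 0.0333 and 0.1 in WT and of at least 2.98 in the others, with single libraries at 0.16 or less and at 2.88 or more. AT3G44006 was listed at 0 in WT and FyPP3DN and had means of 2.13 to 3.07 in nrp1 nrp2 and the combination, in which AT3G05945 had means of 0.397 to 1.13, beside 38.9 to 62.6 in WT and FyPP3DN. ALAAT2 had means of 3.96 and 3.71 in the combination and 6.87 to 8.67 elsewhere. In AT3G44006 and AT3G05945 the combination was like nrp1 nrp2, and in MMZ3 and AT4G05275 unlike FyPP3DN.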
